A study of Mus musculus with 92 samples.

How the data were processed

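Of 92 samples in the labels, 26 were analysed: 12 RNA-seq and 14 SLAM-seq libraries of mouse embryonic stem cells with a dTAG degron on GABPA, GABPB1, or GABPB1 and GABPB2, in 13 groups of 2 libraries. The other 66 samples, which are of other assays, were not used here. Per the labels' protocols, cells received 500 nM dTAG-13 or DMSO for 1, 2, 4 or 12 h, and SLAM-seq cells were labelled with 500 µM 4-thiouridine. Groups were taken from the labels, and the DMSO group labelled for 2 h served both 2 h and 4 h.

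For RNA-seq, the deposited tables hold expected counts per gene in the sense of RSEM, that is, estimated counts that include fractions. Per the submitters' processing notes, the tools listed for these samples were Trim Galore 0.6.7, cutadapt 3.5, STAR 2.7.11a, RSEM 1.3.1, Bowtie2 2.4.4, Picard 2.21.4, SAMtools 1.13, deepTools 3.5.1 and DESeq2 1.44.0. For SLAM-seq, the deposited tables hold a count of all reads and a count of reads with T-to-C conversions per gene interval, made per the file headers with slamdunk 0.4.3 on GENCODE basic gene intervals, with the genome mm39 per the labels. The same deposited tables hold CPM values that slamdunk made per the file headers by dividing by all mapped reads, and these served here only to compute the share of reads in gene intervals, while CPM values in the report were computed from the counts with edgeR. The handling of strands and of reads in overlapping genes is not given in the sources used here. Gene symbols came from an Ensembl name table. Of 56953 gene IDs, 52029 received a symbol and 4924 did not, and 65 symbols belonged to more than 1 ID, which were kept as separate genes.

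Expected counts were rounded to whole numbers, and the converted-read counts were used for SLAM-seq. RNA-seq totals were 16.0 to 32.1 M counts per library, and SLAM-seq libraries held 0.94 to 4.25 M converted reads, which were 5.06% to 14.12% of all reads. Each assay was fitted once with edgeR 4.0.16 (R 4.3.3), with a mean per group, TMM normalization and genes kept by filterByExpr (a minimum count of 10 and a total of 15), which left 16396 genes for RNA-seq and 15887 for SLAM-seq. The common biological coefficient of variation was 0.0608 and 0.143. Genes were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes tested, and called at an adjusted p under 0.05. Standard errors are those implied by the test: the absolute log2 fold change divided by the square root of the quasi-likelihood F statistic. There were 11 comparisons, of which 4 were differences: the response of the GABPA line minus that of each other line, the 12 h response minus the 1 h response, and 4 h minus 2 h of dTAG-13. Overlaps of calls were tested with Fisher's exact test, one-sided, beside the overlap of independent lists of the same sizes (33 overlaps).

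For simulated data with known changes, the test called 78.8%, 88.1% and 98.5% of genes changed by 0.585, 1 and 2 on the log2 scale in RNA-seq of the GABPA line, and 14 of 15857 unchanged genes. In SLAM-seq at 1 h the shares were 4.5%, 28.4% and 62.7%, with 0 of 15318 unchanged genes called by edgeR and 1 by DESeq2. Replicates differed by more than counting error in every group (chi-square per degree of freedom of 1.96 to 16.1).

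Gene lists, 22 in number, were fixed before the data were examined and tested with camera (limma 3.58.1, preset correlation of 0.01) with adjustment over the lists of a comparison, beside camera with an estimated correlation and fry. The number of members called was also counted with the adjustment over the list alone. A further 5 lists were chosen after the data were seen and stand only in the closing section.

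Genes were named by a rule fixed before the data were examined. For each comparison with DMSO it named the GABP subunits and the 10 genes with the largest rise and fall among called genes with an average log2 CPM of at least 3 and no overlap between dTAG-13 and DMSO libraries. Predicted genes, clone names and pseudogenes named as such were left out, as were IDs with no symbol, and 1 gene that the rule named is not reported here. It also named up to 4 members of each list that passed camera and of the Integrator and naive pluripotency lists, and the 10 genes with the smallest p that fell at 1 h. For differences it named the 5 genes with the smallest p in each direction, with no overlap between the responses of the libraries. Where a group had no reads, the change is given as at least the ratio to a floor of 3 reads over the group, and with 1 to 3 reads as a ratio with a 95% interval. These floors and intervals cover counting error only. The responses at 2 h and 4 h were compared with 20 simulated sets of unchanged groups against the same controls.

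Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2 size factors in edgeR, no low-count filter, a minimum average log2 CPM of 3, a fit of the libraries of the comparison alone, a block for replicate number, leaving out each library in turn, converted reads scaled by total reads, and all reads in place of converted reads. Fits without the 12 h libraries, without abundant and mitochondrial genes, and of genes tested in both assays were added after the data were seen. No cells without a degron were treated with dTAG-13 and no unlabelled cells were used here, so effects of the compound itself and background conversions were not measured. Tables were handled with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.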

Results

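Mouse embryonic stem cells of the C57BL/6 background carried a dTAG degron, a protein tag through which the small molecule dTAG-13 sends the tagged protein to the proteasome. The tag was on GABPA, the ETS-family subunit that binds DNA, on GABPB1, a partner subunit, or on GABPB1 and its paralog GABPB2 together. Cells received 500 nM dTAG-13 or the solvent DMSO. Polyadenylated RNA-seq covered the 3 lines at 12 h in 6 groups (12 libraries). SLAM-seq, which marks newly made RNA with 4-thiouridine (500 µM) so that labelled reads carry T-to-C conversions, covered the GABPA line at 1, 2, 4 and 12 h in 7 groups (14 libraries). The 2 h and 4 h samples shared 1 DMSO group, labelled for 2 h. Every group had 2 libraries, which the labels call biological duplicates. P-values rest on the spread between replicates, estimated over all groups of an assay and not only those compared. That spread was unequal, with a chi-square per degree of freedom against counting error of 3.12 in the GABPB1 DMSO group and 16.1 in the GABPB1/GABPB2 DMSO group. P-values may therefore be too small for some comparisons and too large for others. RNA-seq totals were 16.0 to 32.1 M counts per library, and replicates correlated at Pearson's r of 0.988 to 0.993 across genes. SLAM-seq libraries held 11.5 to 30.7 M reads, of which 0.94 to 4.25 M were converted. On simulated data, the test recovered 78.8% of 66 genes changed by 0.585 on the log2 scale for RNA-seq of the GABPA line, and 4.5% for SLAM-seq at 1 h. For genes changed by 2 on the log2 scale the shares were 98.5% and 62.7% of 67 genes. Fold changes below are log2 values from edgeR, dTAG-13 over DMSO, with the standard errors implied by the test statistic. Adjusted p-values are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (n = 2 against 2).

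**Figure D1:**
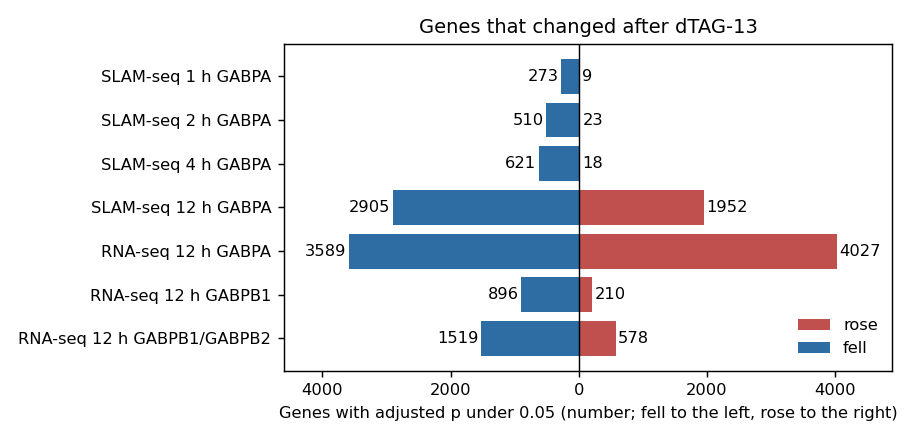
Number of genes with an adjusted p under 0.05 after dTAG-13 in each comparison (2 libraries against 2), with genes that fell to the left of 0 and genes that rose to the right. The bars run from 273 fallen and 9 risen genes in SLAM-seq at 1 h to 3589 fallen and 4027 risen genes in RNA-seq of the GABPA line at 12 h. Calls use the spread pooled over all groups of an assay. Fits of each line alone reversed the order of the GABPB1 and GABPB1/GABPB2 lines by number of calls.

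The mRNAs of the GABP subunits were examined in every line. Because the degron removes protein, these mRNA levels do not check the labels. In the GABPA line, Gabpa mRNA (ENSMUSG00000008976.17, mm39 chromosome 16, 84631813 to 84660667) was at 48.9 and 46.4 CPM in DMSO and at 64.6 and 70.0 CPM after 12 h of dTAG-13 (0.50 ± 0.0768, adjusted p = 4.34e-05). Gabpb1 rose by 1.62 ± 0.1 (adjusted p = 7.77e-10) and Gabpb2 by 0.85 ± 0.0718 (adjusted p = 4.2e-08) in the same cells. In the GABPB1 line, Gabpb1 rose by 0.74 ± 0.0997 and Gabpa by 0.38 ± 0.0678, while Gabpb2 changed by 0.16 ± 0.0695, which did not pass (adjusted p = 0.216). In the GABPB1/GABPB2 line, Gabpa, Gabpb1 and Gabpb2 rose by 0.60, 0.92 and 0.37, and the Gabpb2 call was lost without dTAG-13 replicate 1 (adjusted p = 0.0516). In DMSO, Gabpa mRNA was higher in the GABPB1 line (142 and 143 CPM) and the GABPB1/GABPB2 line (144 and 161 CPM) than in the GABPA line. In SLAM-seq, Gabpb1 rose at 2 h (1.21 ± 0.154, adjusted p = 2.18e-05), 4 h (1.20 ± 0.155) and 12 h (1.08 ± 0.147). Gabpa rose at 2 h (0.99) and 4 h (0.83). The 4 h call was lost without DMSO replicate 2 (adjusted p = 0.0725) or dTAG-13 replicate 1 (adjusted p = 0.0969), and Gabpa was at 0.12 at 12 h (adjusted p = 0.631). At 1 h neither Gabpa (0.58, adjusted p = 0.193) nor Gabpb1 (0.52, adjusted p = 0.165) passed. Gabpa, Gabpb1 and Gabpb2 have antisense neighbours (Atp5j, Gm27003 and Gm16740), and reads of the partners cannot be told apart because strand handling was not stated.

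The first comparison asked which RNAs changed in amount 12 h after GABPA loss. In RNA-seq, 4027 of 16396 genes rose and 3589 fell, of which 1125 and 1280 moved by more than 2-fold. The largest falls included Exoc3, which encodes an exocyst subunit (ENSMUSG00000034152.7, mm39 chromosome 13, 74317607 to 74356851), from 53.2 and 54.2 CPM to 0.805 and 1.06 CPM (-5.83 ± 0.156, adjusted p = 3.47e-14). Exosc3, which encodes an RNA exosome subunit (ENSMUSG00000028322.12, chromosome 4, 45316613 to 45342732), changed by -5.09 ± 0.133 and overlaps Dcaf10 on the other strand. Slc35c2 (-5.36), Myg1 (-5.17, an exonuclease gene overlapping Pfdn5), Fibp (-5.11), Rps6kc1 (-5.05) and the acyl-protein thioesterase gene Lypla2 (-5.04) fell in the same range. So did the inositol polyphosphate phosphatase gene Minpp1 (-5.02) and the ETS-family gene Etv3 (-4.90). Rian, an imprinted noncoding RNA, had 7 reads in DMSO and none after dTAG-13, at least 2.08-fold lower against a floor of 3 reads over the group. Its call was lost without DMSO replicate 2 (adjusted p = 0.085), dTAG-13 replicate 1 (0.0539) or dTAG-13 replicate 2 (0.0574). Among the largest rises were Synm (3.30 ± 0.196, synemin), Ddit4 (3.20 ± 0.117, an inhibitor of mTORC1), Zfp750 (3.08), Tap1 (3.03, the antigen peptide transporter), and Cnga3 (2.92). Others were Trp73 (2.90, a member of the p53 family), Ddit4l (2.83), the kinase gene Plk2 (2.68), Zfp365 (2.57) and Ephx1 (2.42, epoxide hydrolase). Ddit4 (ENSMUSG00000020108.5, chromosome 10, 59785491 to 59787656) went from 44.8 and 40.2 CPM to 429 and 354 CPM. Synm, Zfp750, Tap1 and Trp73 have antisense neighbours and carry the same uncertainty of strand.

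Gene lists fixed before the data were examined were tested against all other genes with camera. All 30 p53 targets measured rose 12 h after GABPA loss (30 also when adjusted over the list alone, camera adjusted p = 1.08e-39, adjusted p = 0.0195 with an estimated correlation), with a median of 1.46 and, for example, Btg2 at 2.29 ± 0.0762, Plk2 at 2.68 and Sesn2 at 1.52. Of 49 genes of DNA replication and the G1/S transition, 35 fell, 1 rose and 13 were not called (35 fell and 1 rose when adjusted over the list alone, camera adjusted p = 2.84e-09, adjusted p = 0.0325 with an estimated correlation), among them the clamp loader genes Rfc2 (-1.99) and Rfc3 (-2.31) and the thymidylate synthase gene Tyms (-1.98). Of 48 genes of mitochondrial DNA expression and protein import, 28 fell, 3 rose and 17 were not called (28 and 4 when adjusted over the list alone, camera adjusted p = 4.79e-10, adjusted p = 0.0382 with an estimated correlation). Timm23 (-2.84), the helicase gene Twnk (-2.24) and Timm10 (-2.18) led that list. Of 84 mitochondrial ribosome genes, 39 fell, 7 rose and 38 were not called (39 and 7 when adjusted over the list alone, camera adjusted p = 3.32e-07, adjusted p = 0.525 with an estimated correlation), with Mrpl53 at -4.21 and Mrpl27 at -3.72. Of 37 proteasome genes, 10 fell and 4 rose (10 and 4 when adjusted over the list alone, camera adjusted p = 0.00376, adjusted p = 0.551 with an estimated correlation), led by Psmb4 at -2.92. Of 21 mitochondrial tRNA synthetase genes, 7 fell and 1 rose (6 and 1 when adjusted over the list alone, camera adjusted p = 0.0479, adjusted p = 0.202 with an estimated correlation), led by Rars2 at -2.67 and Hars2 at -2.36. Of 25 immediate early genes, 11 rose and 2 fell (11 and 4 when adjusted over the list alone, camera adjusted p = 0.0315, adjusted p = 0.618 with an estimated correlation), and the members with the smallest p were Btg2, which is also a p53 target, Jun (1.43) and Fosl1 (3.99). The median of that list was 0.26, and -0.02 without the low-count filter.

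The remaining lists did not pass camera in this comparison. Among 17 Integrator genes, which encode the complex that cleaves nascent RNA, Ints12 (-1.42 ± 0.0976), Ints11 (-0.94 ± 0.0731), Ints5 (-0.56) and Nabp2 (-0.46) fell, 1 rose and 12 were not called (4 and 1 when adjusted over the list alone, camera adjusted p = 0.266). Of 10 reported GABP targets, 5 fell and 1 rose (5 and 2 when adjusted over the list alone; adjusted p = 0.266). Among 77 oxidative phosphorylation genes, 25 rose and 21 fell (26 and 21 when adjusted over the list alone; adjusted p = 0.667), and the median (0.09) and the mean (-0.07) differed in sign. Of 79 cytosolic ribosomal protein genes, 41 rose and 13 fell (43 and 13; adjusted p = 0.166), and of 33 pausing and elongation factor genes, 8 rose and 9 fell (8 and 9; adjusted p = 0.411). Of 14 ETS family genes, 5 rose and 6 fell (5 and 6; adjusted p = 0.293). Of 28 naive and general pluripotency genes, 8 rose, 10 fell and 10 were not called (8 and 10; adjusted p = 0.845), including Trim28 (-0.45), Nr0b1 (-0.44), Lin28a (-0.37) and Stat3 (0.44). Of 15 formative and primed pluripotency genes, 3 rose and 4 fell (3 and 4; adjusted p = 0.845). Of 23 lineage markers, 3 rose and 5 fell (3 and 4; adjusted p = 0.845), and their median and mean differed in sign. Of 12 feeder fibroblast markers, 3 rose and 9 were not called (1 rose when adjusted over the list alone; adjusted p = 0.42), and all 12 measured 2-cell-like genes were not called (adjusted p = 0.845). The integrated stress response list had 13 of 35 genes that fell and 5 that rose (14 and 5; adjusted p = 0.534), the G2/M list 10 of 40 that fell and 5 that rose (10 and 5; adjusted p = 0.751), and the heat shock list 8 of 13 that rose and 3 that fell (8 and 3; adjusted p = 0.295). The GABP subunits, 3 genes that all rose, were too few for a set test.

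The second comparison addressed loss of GABPB1 alone at 12 h. In RNA-seq, 210 genes rose and 896 fell, and 18 and 104 of them moved by more than 2-fold. Lypla2 (ENSMUSG00000028670.15, chromosome 4, 135695535 to 135699937) fell most, from 45.1 and 40.5 CPM to 5.38 and 6.11 CPM (-2.89 ± 0.131, adjusted p = 2.33e-09). Exoc3l (-2.19), Tro (-1.66), the deubiquitinase gene Usp11 (-1.65), the Rab5 effector gene Rabep2 (-1.61), and Rinl (-1.58) followed. Tmem184c (-1.56), the immunoproteasome gene Psmb10 (-1.55), Minpp1 (-1.44) and Ccdc137 (-1.41) came next. The rises were smaller: Rnf157 (1.04 ± 0.121), Cpe (0.90), Dixdc1 (0.78), Commd3 (0.75) and Gabpb1 itself. Others that rose were Cgref1 (0.73), Slc9a8 (0.70), Ano3 (0.70), Bbs7 (0.66) and Dap (0.65). Of the lists, 8 of 49 DNA replication genes fell (12 when adjusted over the list alone, camera adjusted p = 1.34e-06, adjusted p = 0.151 with an estimated correlation), with Rfc2 at -0.58 and Tyms at -0.57. Of the p53 targets, 5 rose (11 when adjusted over the list alone, camera adjusted p = 4.53e-06, adjusted p = 0.327 with an estimated correlation), with Btg2 at 0.34. In the integrated stress response list, 4 genes rose and 1 fell (8 and 2 when adjusted over the list alone, camera adjusted p = 0.00221, adjusted p = 0.461 with an estimated correlation), Chac1 at 0.84 and Trib3 at 0.41 among them. The mitochondrial ribosome (8 fell; camera adjusted p = 0.0078, adjusted p = 0.703 with an estimated correlation), mitochondrial DNA expression and import (5 fell; 0.0322, adjusted p = 0.461 with an estimated correlation), ETS family (2 fell; 0.0303, adjusted p = 0.306 with an estimated correlation) and formative pluripotency lists (3 fell; 0.0078, adjusted p = 0.306 with an estimated correlation) passed as well. Nabp2 (-0.36) was the Integrator gene that fell (camera adjusted p = 0.155). Leaving out any 1 of the 4 libraries, which leaves 1 in its group, lowered both counts. The drop was similar for each library, so the counts did not rest on a particular one. Ano3, Bbs7, Cgref1, Commd3, Cpe and Dixdc1 lost their calls without at least 1 of them (adjusted p of 0.052 to 0.199). A fit of these 4 libraries alone gave 1240 risen and 1947 fallen genes.

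The third comparison addressed joint loss of GABPB1 and GABPB2. In RNA-seq at 12 h, 578 genes rose and 1519 fell, of which 37 and 351 moved by more than 2-fold. These counts, larger than those without GABPB1 alone, rest on the spread pooled over all RNA-seq groups. In fits of each line alone the order reversed, with 222 risen and 1089 fallen genes here against 1240 and 1947 without GABPB1. Lypla2 fell from 43.7 and 33.3 CPM to 1.96 and 2.75 CPM (-4.05 ± 0.171, adjusted p = 8.21e-11), followed by Usp11 (-3.57), Minpp1 (-3.29), Etv3 (-3.16), Exosc3 (-3.12), Kti12 (-3.11, a tRNA modification factor gene that overlaps Txndc12), Exoc3l (-3.10), Tmem184c (-3.06) and Rps6kc1 (-2.78). Pgk1-rs7 had 441 reads in DMSO and none after dTAG-13, at least 114-fold lower against a floor of 3 reads over the group, but it is a copy of Pgk1 and its reads are uncertain. Among the rises, Hsd17b7 (0.75 ± 0.13), Mvd (0.71) and Dhcr7 (0.70) encode enzymes of cholesterol synthesis and Scd1 (0.67) a fatty acid desaturase. Zfp750 (0.94), Gabpb1 (0.92), Chmp2a (0.90, an ESCRT-III subunit gene), Cpe (0.85) and Elmo3 (0.68) rose too. Of the p53 targets, 11 rose (13 when adjusted over the list alone, camera adjusted p = 3.62e-06, adjusted p = 0.401 with an estimated correlation), with Btg2 at 0.47 and Plk2 at 0.46. Of the DNA replication genes, 12 fell (16 when adjusted over the list alone, camera adjusted p = 1.9e-05, adjusted p = 0.24 with an estimated correlation), with Rfc2 at -1.04. The list of mitochondrial DNA expression and import had 16 genes that fell (17 when adjusted over the list alone, camera adjusted p = 0.000507, adjusted p = 0.401 with an estimated correlation), including Timm23 at -1.12. Among mitochondrial ribosome genes, 18 fell and 1 rose (18 and 4 when adjusted over the list alone, camera adjusted p = 0.00723, adjusted p = 0.898 with an estimated correlation), with Mrpl27 at -2.26 and Mrpl53 at -1.84. The integrated stress response list had 9 that fell and 1 that rose (13 and 1; camera adjusted p = 0.0104, adjusted p = 0.898 with an estimated correlation). Ints11 (-0.37) and Nabp2 (-0.43) were the Integrator genes that fell (camera adjusted p = 0.638). Without DMSO replicate 2, 891 genes rose, while 204 rose without dTAG-13 replicate 1, 220 without dTAG-13 replicate 2 and 222 in a fit of these 4 libraries alone. For falls the count was 956 without dTAG-13 replicate 1. Cpe lost its call without dTAG-13 replicate 1 (adjusted p = 0.0701), and Elmo3 without DMSO replicate 2 (0.0564) or dTAG-13 replicate 2 (0.134).

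The responses of the lines were then compared directly, as an interaction between line and treatment. The 12 h response differed between the GABPA line and the GABPB1/GABPB2 line for 3402 genes. It was higher in the GABPA line for 1648 and lower for 1754. The genes with the smallest p among those lower in the GABPA line were Nip7, a ribosome assembly factor gene (difference -2.55 ± 0.0908, from -3.26 without GABPA and -0.71 without GABPB1/GABPB2), the TFIIH helicase gene Ercc3 (-3.40), Psmb4 (-2.09), the ribosome assembly factor gene Ebna1bp2 (-2.24) and Wdr24 (-3.69), each with an adjusted p of at most 1.76e-09. Among those higher in the GABPA line were Ddit4 (2.76 ± 0.163, from 3.20 and 0.44), the antiproliferative gene Btg2 (1.82), Zfp365 (2.10), Ephx1 (1.94) and Plk2 (2.23). Of the p53 targets, 26 of 30 responded more strongly in the GABPA line (27 when adjusted over the list alone), with a median difference of 1.25 (camera adjusted p = 2.38e-52, adjusted p = 0.00837 with an estimated correlation). Of the mitochondrial DNA expression and import genes, 24 were lower in the GABPA line and 1 higher (25 and 1; median -0.47; camera adjusted p = 1.24e-10, adjusted p = 0.0404 with an estimated correlation), as were 20 of 49 DNA replication genes (24 when adjusted over the list alone; median -0.20; camera adjusted p = 1.72e-07, adjusted p = 0.0404 with an estimated correlation). Against the GABPB1 line, 4220 genes differed, 2046 of them higher and 2174 lower in the GABPA line, among them Nip7 (-2.95), Ercc3 (-3.93), Ebna1bp2 (-3.02), Cops7a (-2.75), Wdr3 (-3.36), Btg2 (1.95), Ddit4 (2.87), Zfp365 (2.14), Plk2 (2.34) and Mcam (1.80). In that comparison 27 p53 targets were higher (27 when adjusted over the list alone; median 1.29; camera adjusted p = 2.92e-41, adjusted p = 0.0175 with an estimated correlation). Mitochondrial DNA expression and import genes (26 lower and 1 higher, with the same counts when adjusted over the list alone; median -0.53; adjusted p = 0.0479 with an estimated correlation) and DNA replication genes (20 lower, 22 lower and 1 higher when adjusted over the list alone; median -0.19; adjusted p = 0.0484 with an estimated correlation) were lower. Lists that passed camera against GABPB1/GABPB2 but not with an estimated correlation were the mitochondrial ribosome (2.7e-07, adjusted p = 0.369 with an estimated correlation), the proteasome (9.98e-05, 0.369), immediate early genes (0.00515, 0.567) and mitochondrial tRNA synthetases (0.0191, 0.128). Against GABPB1 they were the mitochondrial ribosome (8.56e-07, adjusted p = 0.526 with an estimated correlation), the proteasome (0.00363, 0.55), mitochondrial tRNA synthetases (0.00963, 0.0942), immediate early genes (0.00959, 0.624) and the integrated stress response (0.0495, 0.67). The lines also differed before treatment, with 10174 of 16396 genes called between the GABPA and GABPB1/GABPB2 lines in DMSO.

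**Figure D2:**
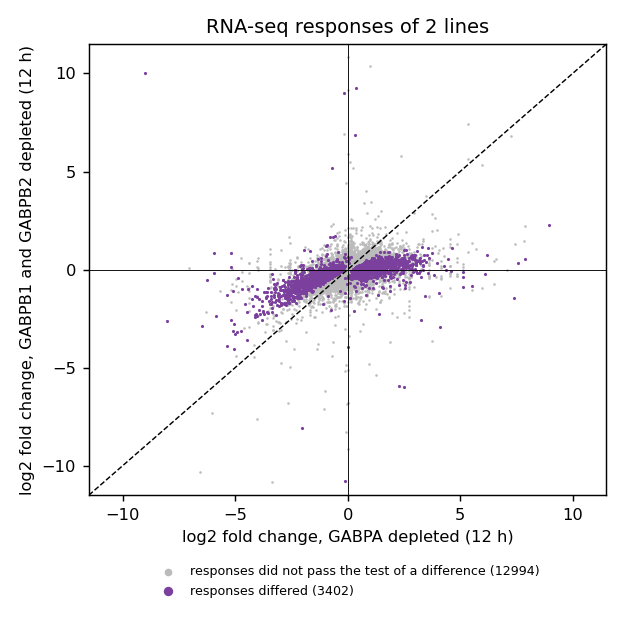
Each point is 1 of 16396 genes, placed by its log2 fold change (12 h dTAG-13 over DMSO, RNA-seq) in the GABPA line on the horizontal axis and in the GABPB1/GABPB2 line on the vertical axis, with the dashed line marking equal changes. The 3402 genes whose responses differed are in purple, among them Ercc3 (GABPA response minus GABPB1/GABPB2 response of -3.40) and Ddit4 (2.76).

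**Figure D3:**
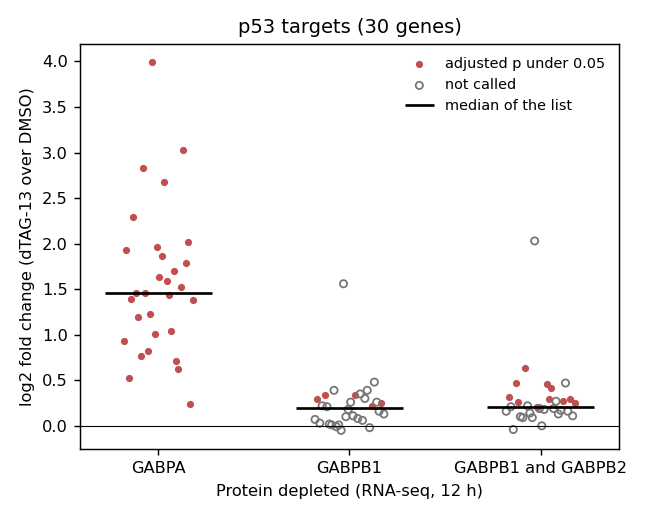
Points are the log2 fold changes (12 h dTAG-13 over DMSO, RNA-seq) of the 30 p53 targets in each line, filled where the adjusted p was under 0.05, and the bars are the medians. All 30 rose without GABPA (median 1.46), 5 without GABPB1 (median 0.20) and 11 without GABPB1 and GABPB2 (median 0.21). Calls use the spread pooled over all RNA-seq groups.

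Overlaps between the lines were larger than independent lists give. Of the 1519 genes that fell without GABPB1/GABPB2, 1385 also fell without GABPA, where independent lists of these sizes share 333 (odds ratio 59.5, Fisher's exact test, one-sided), and 904 were shared without dTAG-13 replicate 1 of the GABPB1/GABPB2 line. Of the 578 that rose, 476 also rose without GABPA (142 for independent lists; odds ratio 16.1). Of the 896 genes that fell without GABPB1, 719 also fell without GABPB1/GABPB2 (83 for independent lists; odds ratio 74.5) and 797 without GABPA (196 for independent lists; odds ratio 36.7). With 1 library left out, these overlaps were 294 to 697 and 294 to 778 genes, and the 476 shared rises were 171 to 630.

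SLAM-seq then asked which newly made RNAs changed first. At 1 h, 273 genes fell and 9 rose among 15887 tested. The smallest p-values belonged to Nip7 (-2), Nifk (-2.25), Tmem208 (-2.72 ± 0.285, adjusted p = 5.45e-06), Bet1l (-2.34), Kti12 (-2.47), Ngrn (-2.65), Rsl24d1 (-1.56), Med10 (-1.60), Pomp (-1.80) and Ddx21 (-1.38). Nip7, Nifk, Rsl24d1 and Ddx21 encode ribosome assembly factors, Med10 a Mediator subunit and Pomp a proteasome assembly factor. The largest falls were Etv3 (-3.25 ± 0.721, adjusted p = 0.0144), Lyrm2 (-3.05), Rwdd2b (-3), Krt10 (-2.90), Zfp825 (-2.82), Zbtb33 (-2.73, the methyl-DNA binding protein Kaiso), Tmem208, Ngrn and Pofut2 (-2.62). Ap1m2 had 28 converted reads in DMSO and 3 after dTAG-13, a ratio of 9.34 (95% counting interval 2.88 to 48). Genes that rose were Rabl2 (2.06 ± 0.534, adjusted p = 0.0457), Rabggta (1.35), Ak1 (1.12), Vhl (1.09), Ginm1 (1.00), Snhg9 (0.99) and Txnip (0.62). The list of mitochondrial DNA expression and import had 9 genes that fell and 39 not called (14 fell when adjusted over the list alone, camera adjusted p = 8.41e-07, adjusted p = 0.00583 with an estimated correlation), with Tfam at -1.06, Tefm at -1.13 and Timm10 at -1.03. Of 83 mitochondrial ribosome genes, 8 fell (15 when adjusted over the list alone, camera adjusted p = 5.8e-05, adjusted p = 0.297 with an estimated correlation), with Mrps23 at -1.75. Psmb4 (-1.43), Psma6 (-1.11) and Psmd6 (-1.03) fell among the proteasome genes (6 when adjusted over the list alone, camera adjusted p = 0.00111, adjusted p = 0.396 with an estimated correlation). Of the reported GABP targets, Tfam fell (3 genes when adjusted over the list alone, camera adjusted p = 0.0106, adjusted p = 0.164 with an estimated correlation). Their median was -0.35, and 0.03 with all reads.

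Further lists, 4 in number, passed camera at 1 h with a positive median while all their members were not called. These were p53 targets (30 genes; camera adjusted p = 0.00377, adjusted p = 0.297 with an estimated correlation), the integrated stress response (31; 0.0131, adjusted p = 0.354 with an estimated correlation), immediate early genes (24; 0.0108, adjusted p = 0.384 with an estimated correlation) and naive pluripotency (28; 0.0312, adjusted p = 0.297 with an estimated correlation). The naive pluripotency median was 0.12, and -0.01 when converted reads were scaled by total reads. Ints12 (-0.91 ± 0.228, adjusted p = 0.0379) was the Integrator gene that fell at 1 h. Leaving out 1 library moved the 1 h count: 112 genes fell without DMSO replicate 1, 157 without DMSO replicate 2, 71 without dTAG-13 replicate 1 and 112 without dTAG-13 replicate 2. Without dTAG-13 replicate 2, 3 genes rose. All 7 named genes that rose, and Etv3, Ap1m2, Lyrm2, Rwdd2b, Zfp825, Zbtb33 and Pofut2 among those that fell, lost their calls without at least 1 of these libraries (adjusted p of 0.0509 to 0.483). The number that rose was 2 when converted reads were scaled by total reads.

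At 2 h, 510 genes fell and 23 rose. Falls included Etv3 (-3.16 ± 0.596, adjusted p = 0.00189), Rnf31 (-3.30, which encodes a linear ubiquitin ligase subunit and overlaps Irf9), Zfp691 (-3), Krt10 (-2.88), the mitochondrial glycine carrier gene Slc25a38 (-2.86), Kti12 (-2.78), Zfp105 (-2.75) and Zfp408 (-2.64). Lyrm2 had 90 converted reads in DMSO and 3 after dTAG-13, a ratio of 24.1 (7.98 to 119), and Fbxw17 had 38 and 2, a ratio of 15.3 (3.94 to 131). Rises besides Gabpb1 and Gabpa were Slc37a2 (1.54 ± 0.387), CT485613.4 (1.09), Fhl1 (1.04), Eef1akmt2 (0.79), Car2 (0.72), Tuba4a (0.61) and Arhgap31 (0.58). At 4 h, 621 genes fell and 18 rose. Krt10 (-4.37 ± 0.504, adjusted p = 4.69e-06), Kti12 (-3.66), the tRNA methyltransferase gene Mettl6 (-3.13), Mrpl53 (-3.09) and Exoc3 (-3) fell. Etv3 had a ratio of 21.4 (7.13 to 106), Slc35c2 17.3 (4.57 to 147), Zfp408 10.1 (3.25 to 50.6), Ybey 8.19 (2.6 to 41.4) and Fbxw17 7.98 (2.53 to 40.4), each of DMSO over dTAG-13 with at most 3 converted reads after dTAG-13. Pappa had the largest rise at 4 h (4.76), which came from 1 library. It was at 395 CPM in dTAG-13 replicate 1 and 10.2 CPM in replicate 2, and at 0.49 without replicate 1 (adjusted p = 0.908). Zfp454 (1.38), Zfp65 (1.00), Rimbp2 (1.00), Exoc3l2 (0.94), Dhx37 (0.80), Pole (0.66) and Idh1 (0.62) rose as well.

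At 2 h the list of mitochondrial DNA expression and import had 9 genes that fell (15 when adjusted over the list alone, camera adjusted p = 3.13e-05, adjusted p = 0.0145 with an estimated correlation), and 13 at 4 h (16; 4.58e-07, adjusted p = 0.00593 with an estimated correlation), with Timm10b at -2.16 and -2.14 and Tomm22 at -1.08 and -1.34. Mitochondrial ribosome genes that fell numbered 18 at 2 h (22; camera adjusted p = 3.13e-05, adjusted p = 0.463 with an estimated correlation) and 20 at 4 h (26; 8.86e-10, adjusted p = 0.0983 with an estimated correlation). Proteasome genes that fell numbered 4 at 2 h (7; camera adjusted p = 0.00301, adjusted p = 0.768 with an estimated correlation) and 7 at 4 h (9; 6.08e-07, adjusted p = 0.514 with an estimated correlation), with Psmb4 at -1.68 and -2.36. At 4 h, 9 of 78 oxidative phosphorylation genes fell (11; camera adjusted p = 0.00235, adjusted p = 0.603 with an estimated correlation), Ndufa13 (-1.64) and Uqcrq (-1.09) among them. All 30 p53 targets were not called at 2 h (camera adjusted p = 0.2) and at 4 h (0.296). Ints12 fell at 2 h (-0.86) and 4 h (-0.87), and Ints11 at 2 h (-0.98). At 2 h, leaving out DMSO replicate 1 gave 90 risen genes, DMSO replicate 2 gave 8 risen and 302 fallen, dTAG-13 replicate 1 gave 10 and 259, and dTAG-13 replicate 2 gave 310 fallen. At 4 h, 40 rose without DMSO replicate 1, 44 without DMSO replicate 2 and 6 without dTAG-13 replicate 1, while 314 fell without dTAG-13 replicate 1 and 330 without dTAG-13 replicate 2. Of the named rises, Gabpb1 and Gabpa at 2 h and Gabpb1 at 4 h kept their calls without any 1 library. The other 7 at 2 h and 9 at 4 h, Gabpa and Pappa among them, lost theirs without at least 1, with adjusted p of up to 0.391 at 2 h and 0.908 at 4 h (Pappa). The same held for Fbxw17, Rnf31, Zfp105 and Zfp408 at 2 h (0.0576 to 0.0907) and Ybey and Fbxw17 at 4 h (0.133 to 0.209). When converted reads were scaled by total reads, 9 genes rose and 766 fell at 2 h, and 6 rose and 1249 fell at 4 h. A replicate block gave 99 risen genes at 2 h and 102 at 4 h, although pairing by replicate number was not established.

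**Figure D4:**
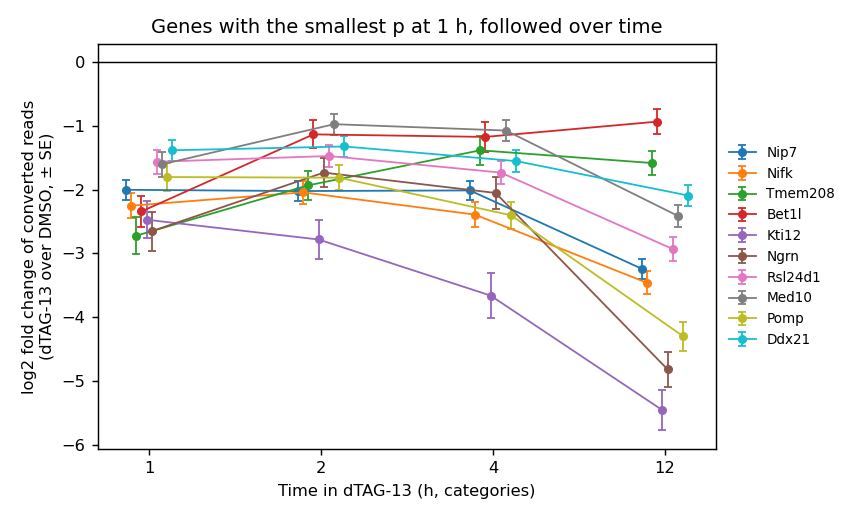
Lines follow the 10 genes that fell at 1 h with the smallest p through 1, 2, 4 and 12 h of dTAG-13 in SLAM-seq, as log2 fold changes of converted reads over DMSO with standard errors (2 libraries against 2 at each time; times are drawn at equal steps). All 10 lay below 0 at every time, and Kti12 went from -2.47 at 1 h to -5.46 at 12 h.

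The 2 h and 4 h responses share DMSO libraries, so their similarity has a part that comes from chance values of those controls. Across 13389 genes, their log2 changes correlated at 0.75, against 0.448 in 20 simulated sets of unchanged groups, and covaried at 0.19 against 0.054. The same sign was seen for 73.3% of genes (65.2% simulated), and 420 genes fell at both times, where independent lists share 19.9 and the simulated sets shared 0. The 2 DMSO libraries were not split between the times, which would leave 1 for each. The simulated sets shared the same controls, and their covariance was at most 0.0565. Sharing as simulated therefore does not account for the excess covariance. For the 420 genes the shared controls may still add to the overlap, because the simulated groups were unchanged. Of the 273 genes that fell at 1 h, whose DMSO group is separate, 206 also fell at 2 h (8.76 for independent lists) and 211 at 4 h (10.7). With 1 library left out, these overlaps were 63 to 172 and 64 to 190 genes, and that of 2 h and 4 h was 234 to 322. Between 2 h and 4 h of dTAG-13, edgeR called 0 genes and DESeq2 called 0. Of 15887 genes tested, 657 had an unadjusted p under 0.05, less than the share of 0.05 that unchanged genes would give. Of 20 lists, 5 passed camera in this comparison and 0 passed with an estimated correlation. How large a change this comparison could find was not simulated, so small differences are not excluded. A replicate block called 5 genes, the fit with no low-count filter 27 and all reads 32. Leaving out 2 h dTAG-13 replicate 2 gave 6 calls and leaving out 4 h dTAG-13 replicate 2 gave 2.

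At 12 h, SLAM-seq gave 2905 fallen and 1952 risen genes. The glycosylation enzyme gene Mogs had 70 converted reads in DMSO and 1 after dTAG-13, a ratio of 94.6 (16.4 to 3790), and Lyrm2 had 91 and 3, a ratio of 41 (13.6 to 202). Exosc3 fell from 96.1 and 85.3 CPM to 1.2 and 2.27 CPM (-5.81 ± 0.339, adjusted p = 7.79e-12), with Krt10 (-5.59), Kti12 (-5.46) and Ublcp1 (-5.41). Also lower were the AMPK subunit gene Prkab1 (-5.28), Ercc3 (-4.93), Mrpl53 (-4.89) and Shq1 (-4.87, an assembly factor of box H/ACA ribonucleoproteins). The adhesion gene Chl1 rose from 13.4 and 21.2 CPM to 244 and 534 CPM (4.47 ± 0.394), with Pm20d1 (3.50), the transcription factor genes Nfia (3.25) and Neurod1 (3.15), Cubn (3.23), Peak1 (3.05), Sowahb (2.97), Ddit4 (2.97) and Hs3st4 (2.86). Ly6a had no converted reads in DMSO and 8 after dTAG-13, at least 1.97-fold higher, and lost its call without DMSO replicate 1 (adjusted p = 0.111), DMSO replicate 2 (0.101) or dTAG-13 replicate 1 (0.105). Of the p53 targets, 23 of 30 rose (23 when adjusted over the list alone, camera adjusted p = 2.41e-16, adjusted p = 0.0114 with an estimated correlation), with Trp53inp1 at 1.64 and Apaf1 at 1.93. Of the DNA replication genes, 34 of 49 fell (38 when adjusted over the list alone, camera adjusted p = 3.12e-14, adjusted p = 0.0114 with an estimated correlation), with Rfc3 at -3.60. Mitochondrial ribosome genes (49 of 83 fell and 1 rose; 56 and 1 when adjusted over the list alone, camera adjusted p = 4.84e-13, adjusted p = 0.035 with an estimated correlation) and those of mitochondrial DNA expression and import (27 of 48 fell; 28 and 1 that rose when adjusted over the list alone; 6.73e-08, adjusted p = 0.00867 with an estimated correlation) fell together. Of 37 proteasome genes, 25 fell (26 when adjusted over the list alone, camera adjusted p = 1.4e-11, adjusted p = 0.0884 with an estimated correlation).

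Further lists passed camera at 12 h. In the integrated stress response list, 16 of 31 genes fell and 3 rose (16 and 3 when adjusted over the list alone, camera adjusted p = 6.33e-06, adjusted p = 0.064 with an estimated correlation), with Nupr1 at -2.21, the asparagine synthetase gene Asns at -1.91 and the serine and folate pathway genes Psat1 and Mthfd2 at -1.68 and -1.92. Of 40 G2/M genes, 19 fell (22 when adjusted over the list alone, camera adjusted p = 0.000215, adjusted p = 0.064 with an estimated correlation), with Cdc20 at -1.48 and Aurka at -1.34. Of 78 oxidative phosphorylation genes, 26 fell and 4 rose (26 and 4 when adjusted over the list alone, camera adjusted p = 0.00304, adjusted p = 0.393 with an estimated correlation). Ints12 (-2.86), Ints11 (-1.46) and Ints9 (-0.52) fell among Integrator genes (camera adjusted p = 0.124). Of the naive pluripotency genes, 9 fell and 4 rose (9 and 4; camera adjusted p = 0.666), including Nr0b1 (-1.21), Tcl1 (-1.45), Nanog (-0.76) and Zfp42 (-0.74). The 12 h dTAG-13 libraries, against which all of these groups were measured, had 7.2% and 9.06% of reads mapping to several places (3.92% and 4.55% in DMSO), 2.35% and 2.42% mitochondrial reads (1.33% and 1.07%), and 10.44% and 13.29% of reads in their 10 most abundant genes (3.69% and 3.76%). Scaling converted reads by total reads gave 617 risen and 4499 fallen genes, so that 87.9% of calls were falls in place of 59.8%. Without DMSO replicate 1, 905 genes rose, and 1268 rose without DMSO replicate 2.

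Of the 273 genes that fell at 1 h, 256 also fell at 12 h in SLAM-seq (49.9 for independent lists; odds ratio 73.7, Fisher's exact test, one-sided p = 1.75e-168). That overlap was 110 genes without 1 h DMSO replicate 1, 150 without DMSO replicate 2, 67 without dTAG-13 replicate 1 and 108 without dTAG-13 replicate 2. Among 12609 genes tested in both assays, 1668 fell at 12 h in SLAM-seq and in RNA-seq of the GABPA line (625 for independent lists; odds ratio 11.9) and 1184 rose in both (453; odds ratio 9.55). Of 253 genes that fell at 1 h and were tested in RNA-seq, 228 fell without GABPA (64.7 for independent lists; odds ratio 28.5) and 192 without GABPB1/GABPB2 (27.7; odds ratio 29.6). With 1 library left out, these were 63 to 226 and 62 to 186 genes, and the overlaps at 12 h were 1293 to 1619 falls and 645 to 1129 rises. Of the 10 genes with the smallest p at 1 h, 9 fell in RNA-seq without GABPA, for example Kti12 (-4.74), Ngrn (-3.89), Nip7 (-3.26) and Pomp (-2.77), and Bet1l did not (0.10, adjusted p = 0.542). Without GABPB1/GABPB2 all 10 fell, with Kti12 at -3.11, Ngrn at -2.24, Nifk at -1.47, Pomp at -1.42, Rsl24d1 at -1.12, Tmem208 at -0.92, Med10 at -0.85, Ddx21 at -0.74, Nip7 at -0.71 and Bet1l at -0.67. Bet1l lost its call without dTAG-13 replicate 1 (adjusted p = 0.0564).

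The 12 h and 1 h SLAM-seq responses differed for 1087 genes, lower at 12 h for 747 and higher for 340. Lower at 12 h were Sssca1 (-4.57 ± 0.364, adjusted p = 8.21e-08), Shq1 (-4.84), the ribosome assembly factor gene Rpf1 (-3.01), Tbrg1 (-2.38) and the pyrimidine synthesis gene Umps (-2.91). Higher at 12 h were Zc3h7a (2.44 ± 0.266, adjusted p = 7.47e-06), Gphn (2.00), Chl1 (4.72), Peak1 (2.47) and Anks1b (2.65), and all of these but Rpf1 overlap other annotated genes. By median, p53 targets were 1.03 higher at 12 h (11 of 30 called; 14 when adjusted over the list alone, camera adjusted p = 3.31e-10, adjusted p = 0.0241 with an estimated correlation). Integrated stress response genes (-0.93; 16 of 31 lower and 1 higher; 18 and 2 when adjusted over the list alone; adjusted p = 0.0241 with an estimated correlation), DNA replication genes (-0.67; 17 of 49; 28 when adjusted over the list alone; 0.0241), G2/M genes (-0.48; 8 of 40; 17 when adjusted over the list alone; 0.0435) and mitochondrial DNA expression and import genes (-0.37; 5 of 48; 8 when adjusted over the list alone; 0.0435) were lower. The mitochondrial ribosome (-0.45, camera adjusted p = 3.02e-07, adjusted p = 0.0921 with an estimated correlation) and the proteasome (-0.58, camera adjusted p = 2.97e-08, adjusted p = 0.175 with an estimated correlation) passed camera but not with an estimated correlation. The 12 h dTAG-13 libraries of this comparison are those with 7.2% and 9.06% of reads mapping to several places. Converted reads were 5.06% to 6.08% of all reads at 1 h and 12.05% to 14.12% at 12 h. Differences in labelling were not separated from differences in response. The count was 516 without 1 h DMSO replicate 2, 427 without 1 h dTAG-13 replicate 2, 518 without 12 h DMSO replicate 1, 651 without 12 h DMSO replicate 2 and 685 without 12 h dTAG-13 replicate 2. Scaling by total reads made 86.9% of calls lower at 12 h in place of 68.7%.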

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

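The tests of interval length, of the p53 proportion and of a common ratio were chosen after the result was seen, and the others were written down before theirs.

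Differences between lines, from a direct test of the interaction, marked 3402 genes between the GABPA and GABPB1/GABPB2 responses and 4220 between the GABPA and GABPB1 responses. Against GABPB1/GABPB2, the response in the GABPA line was higher for Ddit4 (2.76), Btg2 (1.82), Zfp365 (2.10), Ephx1 (1.94) and Plk2 (2.23), and lower for Nip7 (-2.55), Ercc3 (-3.40), Psmb4 (-2.09), Ebna1bp2 (-2.24) and Wdr24 (-3.69). Against GABPB1, it was higher for Btg2 (1.95), Ddit4 (2.87), Zfp365 (2.14), Plk2 (2.34) and Mcam (1.80), and lower for Nip7 (-2.95), Ercc3 (-3.93), Ebna1bp2 (-3.02), Cops7a (-2.75) and Wdr3 (-3.36). Of the lists that passed camera, 7 against GABPB1/GABPB2 and 8 against GABPB1, those that also passed with an estimated correlation were marked. These were p53 targets (median 1.25 against GABPB1/GABPB2 and 1.29 against GABPB1), mitochondrial DNA expression and import (-0.47 and -0.53) and DNA replication (-0.20 and -0.19).

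For the smaller falls without GABPB1/GABPB2, 220 genes that fell at 1 h in SLAM-seq and by over 0.5 in RNA-seq without GABPA were examined. Their GABPB1/GABPB2 change was a median of 0.41 of the GABPA change (quartiles 0.29 and 0.51). Choosing genes by their fall without GABPA may itself lower this ratio. Scatter around 1 common ratio (0.43) was larger than the pooled errors allow (chi-square per degree of freedom 8.82), with 22 genes more than 3 standard errors above the common line and 27 below. With these errors a single factor of reduction does not account for it. The errors were pooled over all RNA-seq groups, and the GABPB1/GABPB2 DMSO libraries differed most. Their chi-square against counting error was 16.1 per degree of freedom, against 3.12 to 6.56 in the other RNA-seq groups. The errors may thus be too small for this line and the scatter overstated. The ratio did not rise with expression (Spearman rho -0.17), so a shrinking of the changes at low counts was not seen. Low counts could also add noise to the ratio without such a trend, which this correlation cannot show. The protein left after dTAG-13 was not measured here, so weaker depletion may account for part of the difference, and the lines also differed in 10174 genes in DMSO.

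The larger rise of p53 targets without GABPA was weighed against a higher starting level in the GABPB1/GABPB2 line, but the median log2 ratio of the 30 targets in DMSO between the lines was 0.03 (quartiles -0.33 and 0.58). A response scaled down in proportion to those falls would give ratios like those of the 220 genes, whereas the p53 targets had a median of 0.17 and an upper quartile of 0.2, which lies below the lower quartile of the 220 genes (0.29). These values suggest that p53 targets did not follow the falls of the 220 genes in proportion. A threshold of cell stress or a later onset could give such values, and neither was tested.

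Differences between times, from a direct test, marked 1087 genes between the 12 h and 1 h SLAM-seq responses. Zc3h7a (2.44), Gphn (2.00), Chl1 (4.72), Peak1 (2.47) and Anks1b (2.65) were higher at 12 h, and Sssca1 (-4.57), Shq1 (-4.84), Rpf1 (-3.01), Tbrg1 (-2.38) and Umps (-2.91) lower. Of 7 lists that passed camera, those that also passed with an estimated correlation were marked, by median p53 targets (1.03), the integrated stress response (-0.93), DNA replication (-0.67), G2/M (-0.48) and mitochondrial DNA expression and import (-0.37).

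The percent of reads that map to several places, a figure outside the main measurement, was 7.2% and 9.06% in the 12 h dTAG-13 libraries, above their DMSO libraries. With the 12 h libraries thinned to the 1.03 M converted reads of the 1 h libraries, 3523 genes were called at 12 h, 12.5 times the number at 1 h. Before thinning, 4857 genes were called, 17.2 times the number at 1 h. The number of converted reads therefore accounts for a part of the larger number of calls, and most of it remained after thinning. Thinning did not equalize labelling: converted reads were 5.06% to 6.08% of all reads at 1 h and 12.05% to 14.12% at 12 h. Background conversions were not measured, so a part of the difference that comes from labelling is not excluded. Of 813 genes that rose at 12 h and lie in intervals of 58.2 kb or more, the upper quartile, 68.6% also rose in RNA-seq (95% exact interval 65.3 to 71.8). The share was 36.6% of all genes in such intervals and 27.2% of all genes. Non-messenger reads in long intervals therefore do not account for the rises shared with RNA-seq. The long genes that did not rise there were not settled. Such intervals held 48.8% of risen and 6.63% of fallen genes. The 12 h dTAG-13 libraries had reads in 43988 and 43084 genes (33774 and 34275 in DMSO). Gene intervals held 50.6% and 47.6% of their mapped reads (55.5% and 55.1% in DMSO). For the 10 protein-coding genes that gained the largest share of reads, from 0.926% to 6.91%, the median RNA-seq change was 0.08 while the SLAM-seq median was 1.11. For these, among them Gphn (0.13 in RNA-seq, 2.38 in SLAM-seq) and Zc3h7a (-0.23 and 2.62), the values are consistent with reads of ribosomal or other non-messenger sequence, although a rise in synthesis not yet seen in total RNA could give the same.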

How the results depend on the processing

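Settings were fixed before the data were examined, except the fits without the 12 h libraries (7 and 231 genes rose and fell at 1 h, 20 and 427 at 2 h, 14 and 591 at 4 h), without abundant and mitochondrial genes (1833 and 3030 at 12 h; 1225 for 12 h minus 1 h) and of genes tested in both assays (2012 and 2411 at 12 h; 1096; overlap 261), which were added after seeing the data and stayed within 1.5 times. Of the values of named genes under DESeq2, 431 kept direction and call and 19 lost the call. With all reads in place of converted reads, 148 SLAM-seq values kept both, 90 lost the call and 4 turned in direction. For lists, an estimated correlation ended 48 of the camera calls and left 177 results as they were. Among SLAM-seq list medians, scaling by total reads moved 92 beyond their spread, reversed 1 and left 27 as they were. All reads moved 56, reversed 1 and left 63 as they were. DESeq2 moved the number of genes that rose to 15 at 2 h and 9 at 4 h. Without the low-count filter, 33 genes rose at 1 h, 50 at 2 h and 49 at 4 h, 27 differed between 4 h and 2 h, and the median of the immediate early genes in RNA-seq of the GABPA line turned to -0.02. With the libraries of the comparison alone, GABPB1 loss gave 1240 and 1947 genes that rose and fell (61.1% falls in place of 81%). GABPB1/GABPB2 loss gave 222 and 1089 (83.1% in place of 72.4%), so the order of these lines by number of calls reversed. In such fits, 16 genes rose at 1 h, and 5 rose and 314 fell at 2 h. Whether replicate numbers pair the libraries was not established: same-numbered libraries correlated at -0.08, 0.03 and 0 in RNA-seq and at -0.03 (1 h), 0.37, 0.15 and 0.11 (2 h and 4 h) and 0.12 (12 h). A replicate block gave 31 risen genes at 1 h, 99 at 2 h and 102 at 4 h, 1811 differing between 12 h and 1 h and 5 between 4 h and 2 h. None of the 225 list medians moved beyond its spread with the block, and the set tests were not run again with it. The simulated unchanged groups for 2 h and 4 h held no effect of replicate number. Scaling converted reads by total reads shifted the median log2 change by -0.135 at 1 h, -0.178 at 2 h, -0.285 at 4 h and -0.342 at 12 h, and gave 2 risen genes at 1 h, 9 and 766 risen and fallen at 2 h, 6 and 1249 at 4 h and 617 and 4499 at 12 h (87.9% falls in place of 59.8%; 86.9% in place of 68.7% for 12 h minus 1 h), with a naive pluripotency median of -0.01 at 1 h. All reads, which include RNA made before treatment, gave 0 and 1 genes at 1 h, 1 and 57 at 2 h, 9 risen at 4 h, 8032 and 7449 at 12 h, 9783 for 12 h minus 1 h, 32 for 4 h minus 2 h, and overlaps of 1 (1 h and 12 h) and 2581 (12 h and RNA-seq). With all reads Rabl2 turned to -0.04, Ap1m2 to 0.01 and Pofut2 to 0.08 at 1 h, Gabpa to -0.62 at 12 h, and the median of reported GABP targets at 1 h to 0.03. For these moved or turned values the cause was not tested, beyond the fewer libraries or other reads that define a setting.

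Leaving out 1 library at a time, with the lone library assumed to vary like the other groups, the counts that rose and fell ranged over 3210 to 3424 and 3044 to 3340 (GABPA, RNA-seq), 33 to 53 and 312 to 375 (GABPB1), 204 to 891 and 956 to 1706 (GABPB1/GABPB2), 3 to 10 and 71 to 157 (1 h), 8 to 90 and 259 to 400 (2 h), 6 to 44 and 314 to 487 (4 h) and 905 to 1668 and 1962 to 2404 (12 h). Differences ranged over 2610 to 3898 (GABPA minus GABPB1/GABPB2), 3276 to 4001 (GABPA minus GABPB1), 427 to 1149 (12 h minus 1 h) and 0 to 6 (4 h minus 2 h), and overlaps over 67 to 251 (1 h and 12 h), 1293 to 1619 (12 h and RNA-seq) and 904 to 1437 (the GABPA and GABPB1/GABPB2 lines). At the depth of the 1 h libraries, 28.4% of 2-fold changes were found in simulated data. The simulated spread was the trend with expression fitted over all SLAM-seq groups, not that of the 1 h libraries, and depth was not separated from spread.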

Other observations

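Lists for 5 processes and the permutation of interval lengths were chosen after the result was seen.

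Of 108 ribosome assembly factor genes, 75 fell and 6 rose in RNA-seq without GABPA (77 and 10 when adjusted over the list alone; camera adjusted p = 7.83e-23, adjusted p = 0.00089 with an estimated correlation). In the same list 23 fell without GABPB1 (5.26e-10, adjusted p = 0.0144 with an estimated correlation) and 36 fell and 1 rose without GABPB1/GABPB2 (3.37e-11, adjusted p = 0.0115 with an estimated correlation). In SLAM-seq, 16 of 107 fell at 1 h (1.31e-12, adjusted p = 0.0295 with an estimated correlation), and 69 fell and 4 rose at 12 h (9.66e-22, adjusted p = 0.00287 with an estimated correlation). Of 21 cholesterol synthesis genes, 20 rose and 1 fell without GABPA (1.91e-07, adjusted p = 0.174 with an estimated correlation), 19 rose without GABPB1/GABPB2 (1.19e-16, adjusted p = 0.0919 with an estimated correlation), 8 rose without GABPB1 (5.26e-10, adjusted p = 0.147 with an estimated correlation) and 12 rose in SLAM-seq at 12 h (2.87e-06, adjusted p = 0.00287 with an estimated correlation). Of 31 Mediator genes, 15 fell and 5 rose without GABPA (0.00975, adjusted p = 0.0575 with an estimated correlation), while in SLAM-seq 3 fell at 1 h (0.000615, adjusted p = 0.0299 with an estimated correlation) and 13 fell and 1 rose at 12 h (0.00257, adjusted p = 0.0456 with an estimated correlation). In between, the list did not pass with an estimated correlation: 3 fell at 2 h (camera adjusted p = 0.00874, 0.0806 with an estimated correlation) and 2 at 4 h (0.0115 and 0.0857). Of 13 RNA exosome genes, 5 fell and 1 rose in RNA-seq without GABPA (0.00375, adjusted p = 0.0806 with an estimated correlation) and 6 fell in SLAM-seq at 12 h (0.000102, adjusted p = 0.018 with an estimated correlation). That list did not pass camera at 1 h (adjusted p = 0.187) or 2 h (0.202), and at 4 h it passed with the preset correlation (0.0294) but not with an estimated one (0.147). Of 9 exocyst genes, 4 rose and 4 fell without GABPA (0.0767), and 3 fell without GABPB1/GABPB2 (0.015, adjusted p = 0.183 with an estimated correlation).

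Genes that fell at 1 h had short intervals, with a median of 9.13 kb (273 genes), against 25.9 kb in random lists matched on expression, of which the shortest had 16.7 kb. A hypothesis was that short genes fall sooner because their transcripts are completed sooner. Genes that fell at 12 h and not at 1 h had a median of 11.8 kb (2649 genes), longer than those of 1 h (permutation p = 0.0069, one-sided, 10000 permutations), as the hypothesis predicts. They too were shorter than their random lists (28.1 kb, shortest 25.2 kb), so the timing does not account for the short intervals of the later genes. The permutation was not matched on expression and cannot tell timing from other differences between early and late genes. Whether timing plays any part was therefore not settled. Among protein-coding genes the medians were 9.58 kb (239 genes that fell at 1 h), 15.4 kb (1987 that fell at 12 h and not at 1 h), 64.3 kb (1667 that rose at 12 h) and 28.2 kb (12001 tested).

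In RNA-seq the first principal component (50.2% of the variance) separated the GABPA line from the other lines.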
